A study of Mus musculus with 7 samples.

How the data were processed

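RNA of Tim4+ resident peritoneal macrophages of C57BL/6 mice was measured in 7 libraries, 3 of steady state and 4 of day 12 after injection of m204 MTO. Groups and replicate numbers came from the sample titles. Per the labels' protocols, live cells were sorted by CD11b, MHC class II and Tim4, RNA came from biological replicates, and 30 ng of total RNA went into poly-A-selected directional libraries (NEBNext Ultra II Directional) sequenced as 100-nt single reads on an Illumina NextSeq sequencer. The extract protocol speaks of 3 biological replicates per condition, while the design text and the sample titles give 4 for day 12. Which libraries shared a day of sorting or library preparation is not given in the sources used here.

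The authors deposited a single table of raw read counts per gene, with no normalisation, 1 column per library and Ensembl identifiers, symbols and coordinates. Per the submitters' processing notes, FastQC, STAR 2.7.11a, SAMtools 1.10, featureCounts (Subread 2.0.6) and DESeq2 1.40.2 were used with the build GRCm39. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. These settings could change values of overlapping genes and of genes with near-identical copies. Such genes are uncertain: Chil3 and Chil4, Lyz1 and Lyz2, Trim43a and Trim43b, the Sprr2a genes, Hspa1a and Hspa1b, and members of the Gbp, H2 and ribosomal protein families. So are genes that overlap another well-expressed gene on the other strand, among them Gpr183 with Ubac2, Slc16a3 with Csnk1d, Rps14 with Ndst1, Gapdh with Iffo1, Ankrd37 with Ufsp2, Cox6c with Vps13b, Irf7 with Phrf1, Lpcat3 with Emg1, Ciita with Dexi and Gata6 with Gata6os. The transcript mt-Nd4l overlaps mt-Nd4 on the same strand. Genes typed as pseudogenes in the table took 4.76% to 5.57% of the counts of a library. Symbols and coordinates were used as the table gives them. Of the 57010 genes, 55404 had a symbol, 147 symbols were shared by more than 1 identifier, and 27238 genes had a read in any library. Every count column was mapped to a sample by its library name.

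The main test was edgeR 4.0.16 (quasi-likelihood, robust, in R 4.3.3) on the deposited counts with TMM factors, the group as the term and Benjamini-Hochberg adjustment at 0.05. Genes entered by filterByExpr with its minimum count of 10 and minimum total of 15, which left 15981 genes. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The common dispersion gave a biological coefficient of variation of 0.219. A change of at least 2-fold is a filter on called genes, and glmTreat on the same fit tested against 1.5-fold. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry. Sums of CPM over markers of another cell type were compared by an exact two-sided permutation test over the 35 splits of 7 libraries. P-values measure the spread between these libraries. Totals of 32077050 to 38586694 counts put the floor of 3 counts per library at 0.0777 to 0.0935 CPM. A fold against a group without any read was computed against 3 counts over the whole group and is a lower bound, and with 1 to 3 reads in a group the ratio carries its exact 95% counting interval.

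The design, the tests, the 34 gene lists (23 on the biology of the study, 2 on handling and RNA quality, 9 on other cell types) and the alternatives were fixed before the data were examined. The rule for named genes was fixed then as well. It took Timd4, Itgam, H2-Ab1, Trem1, Gata6 and Mki67 in every case. It took the 12 largest rises and the 12 largest falls among called genes without overlap of the groups and with at least 5 CPM in the higher group, leaving out predicted genes, identifiers, pseudogenes and receptor segments. It further took the 4 members of each list with the lowest p (2 where none passed) and the 6 genes with the lowest p in each direction. Genes named outside this rule were chosen after their values were seen, which is said where they first appear. The rule and those additions gave 191 genes, and the text names the part of them that it describes. Some items are not reported here. A few list symbols did not match a symbol of the table and are not used here.

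The procedure was tested on simulated counts with the steady-state means and the library sizes of these samples, the same dispersion of each gene in both groups, and 200 genes changed. The filter passed 15308 genes. It recovered 16.7% of the genes changed 1.5-fold (11 of 66), 56.5% of those changed 2-fold (35 of 62) and 87.3% of those changed 4-fold (55 of 63), with 10 false calls among 111. Camera on 34 simulated lists called the 3 that had been shifted and 0 others. Simulated genes were drawn independently, whereas the estimated correlation in the data was, for example, 0.894 in the cell cycle list. The simulation therefore says nothing about camera's false calls in lists of correlated genes. Alternatives were RLE and upper-quartile factors, library totals only, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust step, the replicate number as a block, leaving out each library, and leaving out the marker genes of other cell types. An alternative added after the data were seen removed the trend of each library on transcript length and GC content by loess (span 0.5) before camera, with values from GENCODE M21 transcripts matched by Ensembl identifier for 97.8% of tested genes; no coordinates of that annotation were used. Values of day 12 libraries were also screened with Dixon's test at its 95% critical value for 4 libraries. Alternatives that left out pairs of day 12 libraries chosen by their Chil3 level were run and then dropped, because a measured outcome had picked the pairs, and their results are not reported here. An earlier run of the comparison of day 12 replicate 2 in falling genes applied a stricter limit than the one written before, and under that limit its result was left undecided.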

Results

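Poly-A RNA was sequenced from Tim4+ resident macrophages that had been sorted by flow cytometry from the peritoneal fluid of C57BL/6 mice. Tim4 is a receptor for phosphatidylserine on dying cells and marks long-lived macrophages of the peritoneal cavity. There were 3 libraries from mice in steady state and 4 from mice 12 days after an injection of m204 MTO. The labels do not spell out MTO, and the title of the series names peritoneal colorectal cancer. The sort used antibodies to CD11b, MHC class II and Tim4, with a stated purity over 97%. The deposited table holds raw read counts for 57010 Ensembl genes in GRCm39 coordinates. Total counts were 33429679, 36201021 and 32077050 in steady-state replicates 1, 2 and 3, and 37428258, 38388234, 38586694 and 34578834 in day 12 replicates 1, 2, 3 and 4. A count of 3 in a library, used as the floor of detection, stood for 0.0777 to 0.0935 CPM. Levels are given as CPM, normalised by TMM, and as mean ± SD over n = 3 steady-state and n = 4 day 12 libraries. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

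The comparison asked how the transcriptome of Tim4+ resident macrophages differed 12 days after MTO injection from that of steady state. At day 12 the cells held far more transcripts of the chitinase-like gene Chil3 (from 1.75 ± 0.933 to 22977 ± 17764 CPM), of arginase 1 (Arg1, from 106 ± 21.7 to 5147 ± 1097 CPM) and of the resistin-like gene Retnla (from 104 ± 13.7 to 5294 ± 4076 CPM). Transcripts of apolipoprotein E (Apoe) fell from 16126 ± 2987 to 541 ± 514 CPM, and those of lysozyme 2 (Lyz2, chosen after its values were seen) from 42101 ± 818 to 4624 ± 3767 CPM. Of the lists of interferon gamma response, MHC class II and glycolysis genes, 23 of 31, 8 of 14 and 21 of 32 tested members rose. All 3 lists passed limma's camera test (adjusted p = 3.55e-09, 0.000120 and 5.08e-08), and none with an estimated correlation (adjusted p = 0.671, 0.311 and 0.435 with an estimated correlation). Of 15981 genes tested with edgeR's quasi-likelihood test, 3242 (20.3%) passed an adjusted p of 0.05, of which 1616 rose and 1626 fell. At least 2-fold changes were seen in 1610 of them, 897 higher and 713 lower, and 1125 passed a test against a change of 1.5-fold, 609 higher and 516 lower. Over all 15981 genes tested, the groups did not overlap in 5591, where chance gives 5.71% of genes. The counts were lower with 2 steady-state libraries in place of 3. They came to 1868 genes (961 higher, 907 lower) without steady-state replicate 1, 1804 (900 and 904) without replicate 2 and 1761 (857 and 904) without replicate 3, while the 1.5-fold test gave 687 and 676 genes without replicates 2 and 3.

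**Figure D1:**
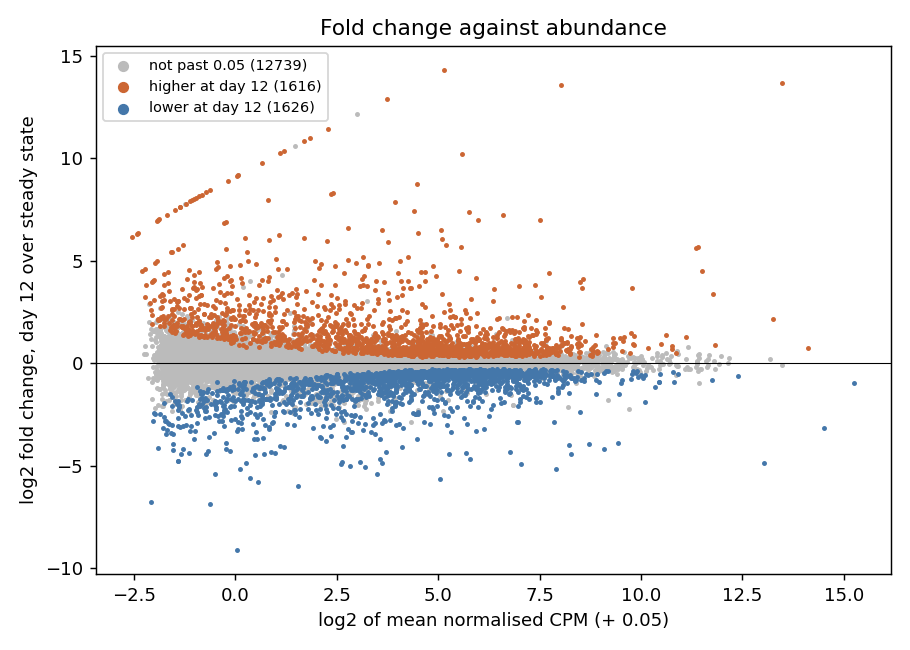
Each point is a tested gene, with the log2 of its mean normalised CPM plus 0.05 on the horizontal axis and its log2 fold change (day 12 over steady state) on the vertical axis. Orange points are the 1616 genes that rose, blue points the 1626 that fell and grey points the rest; the straight line of points at the upper left holds genes without a read in steady state, whose fitted fold is not a measurement.

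The genes used in the sort, and the gene named in the title of the series, came first. Timd4, which encodes Tim4 (ENSMUSG00000055546, chromosome 11, 46701627 to 46735159), fell from 963 ± 80.5 to 495 ± 114 CPM (log2 fold change -0.96, SE 0.17, edgeR adjusted p = 0.00484), with all 4 day 12 libraries below all 3 of steady state. Trem1, a receptor that amplifies inflammatory signals in myeloid cells (ENSMUSG00000042265, chromosome 17, 48539796 to 48553952), rose from 0.667 ± 0.430 to 18.6 ± 13.3 CPM (log2 fold change 4.77, SE 0.70, adjusted p = 0.00344). Day 12 replicate 4 held 38.2 CPM of it, and the log2 fold change was 4.15 without that library and 5.42 without steady-state replicate 2. H2-Ab1, an MHC class II beta chain (ENSMUSG00000073421, chromosome 17, 34476663 to 34488393), rose from 44.4 ± 38.99 to 680.0 ± 324 CPM (log2 fold change 3.94, adjusted p = 0.00892), although steady-state replicate 1 already held 89.4 CPM and the log2 fold change without it was 4.98. Itgam, which encodes CD11b (ENSMUSG00000030786, chromosome 7, 127661812 to 127717663), rose from 1328 ± 124 to 2133 ± 361 CPM (log2 fold change 0.68, adjusted p = 0.0160). That call was lost without steady-state replicate 1 (adjusted p = 0.0703) or 3 (0.082). Gata6, the transcription factor that maintains the large peritoneal macrophage programme, encoded on the strand opposite to the overlapping Gata6os (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635), rose from 175 ± 4.72 to 246 ± 26.3 CPM (log2 fold change 0.49, adjusted p = 0.0148). Its adjusted p was 0.0546, 0.0755 and 0.0747 without steady-state replicates 1, 2 and 3. The proliferation marker Mki67 (ENSMUSG00000031004, chromosome 7, 135291513 to 135318090) stood at 106 ± 63.4 CPM in steady state and 37.8 ± 28.7 CPM at day 12, and did not pass (adjusted p = 0.178).

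**Figure D2:**
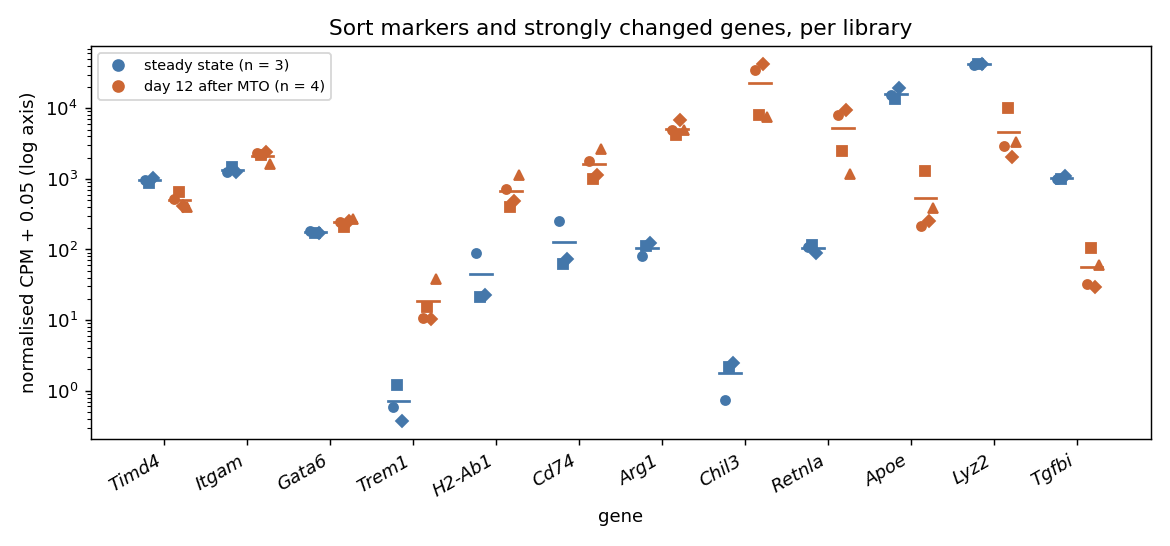
Normalised CPM (plus 0.05, log axis) of 12 genes in each library, blue for steady state (n = 3) and orange for day 12 (n = 4), with bars at the group means and marker shapes for the replicate number (circle 1, square 2, diamond 3, triangle 4). Chil3 and Retnla spread widely among the day 12 libraries while Arg1 stayed within 4161 to 6717 CPM.

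Among the 12 genes picked for the largest rises, several were near or at 0 in steady state. Chil3 (log2 fold change 13.68, edgeR adjusted p = 0.000641) ranged from 7622 CPM in day 12 replicate 4 to 41778 CPM in replicate 3. Its neighbour Chil4, near-identical in sequence and so uncertain in its share of reads, had 4 reads in steady state and 525 ± 397 CPM at day 12. Trim43a and Trim43b, a further pair of related genes, had no steady-state read and reached 70.4 ± 47.5 and 6.38 ± 4.18 CPM. Against a floor of 3 counts over the group they were at least 2362-fold and at least 214-fold higher. On the same floor Sprr2a2, of the small proline-rich family, was at least 326-fold and the ectonucleotidase gene Entpd3 at least 237-fold higher. With no filter on low counts these 2 calls were lost (adjusted p = 0.07 and 0.0857). Their fitted log2 fold changes of 11.44 and 10.99 became as low as 10.75 and 10.16 with 1 library left out, so both bounds lean on single libraries. The ribonuclease gene Rnase2a and Gnao1, a G protein alpha subunit, each had 3 steady-state reads. Rnase2a was 356-fold with a 95% counting interval of 122 to 1728, and lost its call with limma-voom (adjusted p = 0.0824), and Gnao1 was 344-fold with a 95% counting interval of 118 to 1670.2. Mall (log2 fold change 10.18, from 0.0793 ± 0.0854 to 96.5 ± 45.1 CPM), Dixdc1 (7.85), Galnt6 (7.43), an enzyme that starts O-linked glycan chains, and Ahnak2 (7.36, from 0.654 ± 0.279 to 107 ± 72.2 CPM) completed the set. With few steady-state reads some of these folds moved by over 1.5 times when a library was left out. For Chil4, with 4 steady-state reads, the log2 fold change of 13.57 became 12.97 to 17.23 over the fits with 1 library left out. The log2 fold change became 11.52 for Mall and 9.14 for Gnao1 without steady-state replicate 1, 8.56 for Dixdc1 without steady-state replicate 2, 9.19 for Rnase2a without steady-state replicate 3, and 7.30 for Rnase2a and 6.79 for Galnt6 without day 12 replicate 3.

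Rises with the lowest p were tighter between libraries. The long non-coding RNA 1700016F12Rik (ENSMUSG00000104955, chromosome 5, 96997364 to 97000797) rose from 0.101 ± 0.0643 to 44.6 ± 8.15 CPM (log2 fold change 8.76, SE 0.33, edgeR adjusted p = 3.35e-06). Arg1 (ENSMUSG00000019987, chromosome 10, 24791119 to 24803382) had a log2 fold change of 5.61 (SE 0.25, adjusted p = 9.15e-06). The lipid-binding receptor gene Cd300lf rose by 3.39 and the potassium channel gene Kcnn3 by 3.67 on the log2 scale. Ucp1, the mitochondrial uncoupling protein of brown fat, rose from 1.33 ± 0.226 to 71.9 ± 20.2 CPM (log2 fold change 5.75, adjusted p = 1.30e-05).

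The genes picked for the largest falls included Robo2, a receptor for Slit proteins (log2 fold change -6.00), Pear1 (-5.65), Cuedc1 (-5.42), F13a1 (-5.17), Apbb1 (-5.06), Bhlhe41 (-5.01), Hal (-4.92), Apoe (-4.90), Gpr183 (-4.90), Sema6d (-4.85) and Rnf150 (-4.81). Without day 12 replicate 2 the log2 fold changes of Robo2, Pear1, Cuedc1, Hal and Apoe were -7.13, -6.33, -6.01, -5.83 and -5.78, and that of Lyz2 was -3.90 in place of -3.19. F13a1, the A chain of coagulation factor XIII, fell from 464 ± 148 to 12.9 ± 8.01 CPM (edgeR adjusted p = 0.000945). Apoe, a lipid carrier secreted by macrophages (ENSMUSG00000002985, chromosome 7, 19430034 to 19433113), had an SE of 0.71 and an adjusted p of 0.00368, and its highest day 12 value was 1303 CPM in replicate 2. Hal, which degrades histidine, fell from 256 ± 33.8 to 8.41 ± 8.11 CPM. The oxysterol receptor gene Gpr183 (ENSMUSG00000051212, chromosome 14, 122189963 to 122202607) had the lowest p of all genes tested (adjusted p = 3.35e-06) and fell from 23.8 ± 0.362 to 0.792 ± 0.157 CPM. Gpr183 lies within Ubac2 on the other strand, which leaves its level uncertain because the strand setting of the counting is not given in the sources used here. Fscn1, an actin-bundling protein (log2 fold change -4.35, from 208 ± 43.1 to 10.2 ± 2.23 CPM), and the laminin chain gene Lama3 (-4.69, from 106 ± 12.9 to 4.08 ± 1.58 CPM) were also among the 6 falls with the lowest p.

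Genes of resident peritoneal macrophage identity went both ways. Of this list, 9 of 31 tested members rose and 5 fell (9 and 10 adjusted over the list alone), with Klf4 (from 70.9 ± 12.2 to 471 ± 109 CPM), Aspa (from 53.3 ± 5.50 to 222 ± 25.6 CPM) and Bhlhe40 (from 206 ± 12.3 to 483 ± 61.4 CPM) higher. Alox15, Icam2 and Prg4, named after their values were seen, did not pass. Alox15 stood at 8649.6 ± 335 CPM in steady state and 9782 ± 710.1 CPM at day 12, and Prg4, which encodes lubricin, at 11823 ± 637 CPM in steady state and 10974 ± 567 CPM at day 12. The falling members numbered 3 without steady-state replicate 1 or 2 and 8 without day 12 replicate 2 or with DESeq2. The list as a whole did not pass camera (adjusted p = 0.564, median log2 fold change -0.04, mean 0.05). Fry, which compares it with no change, called it higher (fry adjusted p = 0.0135). Among genes of monocyte-derived and small peritoneal macrophages, 6 of 22 tested members rose and 8 fell (8 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.776, median -0.05, mean 0.78). Chil3 and Retnla were among the rising members and Lyz2, S100a4 (from 10.2 ± 1.03 to 2.98 ± 0.576 CPM) and Folr2 (from 32.9 ± 4.65 to 13.7 ± 1.83 CPM) among the falling ones. The monocyte chemokine receptor gene Ccr2, chosen after its values were seen, fell from 11.8 ± 1.24 to 5.19 ± 1.99 CPM (adjusted p = 0.0114, but 0.0523 without steady-state replicate 2). Plac8 of the same list, likewise chosen after its values were seen, rose from 0.727 to 66.3 CPM (log2 fold change 6.51, edgeR adjusted p = 0.01755). Its call was lost without steady-state replicate 1 (adjusted p = 0.0588), 2 (0.0730) or 3 (0.0744), with no filter on low counts (0.0684) and with limma-voom (0.188). Without steady-state replicate 3, only 3 members of that list rose and 5 fell.

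Part of the MHC class II and interferon response genes rose. Of the MHC class II list, 8 of 14 tested members rose and 0 fell (9 and 0 adjusted over the list alone). These included H2-Aa (from 41.8 ± 36.2 to 714 ± 255 CPM, log2 fold change 4.09, edgeR adjusted p = 0.00575), the invariant chain gene Cd74 (from 129 ± 106 to 1641 ± 757 CPM, named after its values were seen) and Ciita, the master regulator of the class II genes (from 2.22 ± 1.35 to 36.2 ± 18.9 CPM), which overlaps Dexi on the other strand. Steady-state replicate 1 held 83.6 CPM of H2-Aa and 251 CPM of Cd74, more than the other steady-state libraries, and without it the log2 fold changes of H2-Aa, Cd74 and Ciita were 5.11, 4.61 and 4.65. The list passed camera (camera adjusted p = 0.000120, and adjusted p = 0.311 with an estimated correlation). In the interferon gamma list, 23 of 31 tested members rose and 1 fell (26 and 1 adjusted over the list alone). The guanylate-binding protein genes Gbp2 (from 73.6 ± 3.92 to 240.0 ± 78.4 CPM) and Gbp3 (from 128 ± 6.37 to 278 ± 40.7 CPM), whose family members can share reads, were higher, whereas Irf8, a transcription factor of mononuclear phagocytes, was the member that fell (from 126 ± 12.97 to 13.6 ± 6.04 CPM). This list passed camera with a median log2 fold change of 1.53 (camera adjusted p = 3.55e-09, and adjusted p = 0.671 with an estimated correlation). Its rising members numbered 11 without steady-state replicate 2, 11 without replicate 3 and 13 with no filter on low counts. Of the type I interferon list, 11 of 37 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 0.000102, and adjusted p = 0.694 with an estimated correlation). Fry did not call the type I list (adjusted p = 0.148), and its mean log2 CPM in day 12 replicate 3 (4.48) lay within the steady-state range of 4.39 to 4.84, against 5.41 to 5.83 in the other day 12 libraries. Oasl1 (from 1.87 ± 0.514 to 13.4 ± 2.96 CPM) and Stat2 (from 81.2 ± 10.7 to 175 ± 38.9 CPM) were among its rising members. Its rising members numbered 6 without steady-state replicate 2 and 23 without day 12 replicate 3, and 2 members fell without day 12 replicate 2. Of the B cell markers, 11 of 18 tested members rose and 1 fell (15 and 1 adjusted over the list alone), with Ighm from 4.30 ± 1.00 to 14.1 ± 5.51 CPM among the rising ones and Bank1 the member that fell (from 75.5 ± 2.83 to 25.4 ± 9.09 CPM). Rising B cell markers numbered 7 without steady-state replicate 2 or 3 and 6 with a filter of 1 CPM, and 2 fell without day 12 replicate 4.

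Alternative activation genes, the set that interleukin 4 induces in macrophages, also rose in part. Of these, 10 of 20 tested members rose and 4 fell (13 and 5 adjusted over the list alone), and the list passed camera with a median log2 fold change of 1.47 (camera adjusted p = 0.000139, and adjusted p = 0.311 with an estimated correlation). Besides Arg1, Chil3 and Retnla, the transcription factor gene Tfec (from 9.01 ± 0.970 to 38.2 ± 3.43 CPM) and the cytokine signalling inhibitor gene Cish (from 1.61 ± 0.214 to 10.1 ± 2.10 CPM) were higher. The cationic amino acid transporter gene Slc7a2 and the lectin gene Mgl2 were chosen after their values were seen. Slc7a2 rose from 246 ± 22.8 to 5588 ± 2623 CPM and Mgl2 from 12.7 ± 4.21 to 155 ± 106 CPM. Of the same list, fibronectin (Fn1) fell from 51916 ± 4161 to 26575 ± 6251 CPM and the mannose receptor gene Mrc1 from 79.1 ± 19.2 to 32.4 ± 10.5 CPM, both likewise named after their values were seen, and the Mrc1 call was lost without steady-state replicate 3 (adjusted p = 0.0501). Among immune checkpoint and suppressive ligands, 11 of 27 tested members rose and 2 fell (12 and 4 adjusted over the list alone) (camera adjusted p = 0.00846, and adjusted p = 0.311 with an estimated correlation). Cd274, which encodes PD-L1, rose from 11.4 ± 0.959 to 100.2 ± 25.5 CPM (log2 fold change 3.13, adjusted p = 6.86e-05) and the interleukin 1 receptor antagonist gene Il1rn from 2.40 ± 0.348 to 10.8 ± 2.68 CPM. Il10, named after its values were seen, was at 0.462 ± 0.190 CPM in steady state and 0.359 ± 0.190 CPM at day 12 and did not pass. Without steady-state replicate 2 or 3 the rising members of the checkpoint list numbered 7, and the falling ones numbered 0 with any 1 steady-state library left out, 1 without day 12 replicate 1, 6 without day 12 replicate 4 and 4 with DESeq2 or with no robust step.

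Inflammatory genes gave a mixed picture. In the TREM1 and DAP12 list, 6 of 14 tested members rose and 2 fell (6 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.201). Pglyrp1, a peptidoglycan recognition protein that binds TREM1, rose from 6.43 ± 0.367 to 115 ± 37.5 CPM and Trem3 from 0.118 ± 0.0573 to 1.68 ± 1.04 CPM. Trem2, named after its values were seen, fell from 37.4 ± 11.7 to 12.3 ± 3.90 CPM, as did the inflammasome gene Nlrp3 (from 65.6 ± 5.60 to 23.5 ± 2.94 CPM). Rising members numbered 3 with any 1 steady-state library left out, and 4 members fell without day 12 replicate 4. Of the NF-kB list, 12 of 32 tested members rose and 3 fell (13 and 5 adjusted over the list alone) (camera adjusted p = 0.0593). Il6 rose from 1.67 ± 0.341 to 19.9 ± 4.55 CPM, Il1a from 5.50 ± 0.895 to 23.5 ± 4.14 CPM and the acute phase gene Saa3 from 3564 ± 412 to 15821 ± 3304 CPM. Il1b (0.388 ± 0.183 CPM in steady state and 0.697 ± 0.721 CPM at day 12) and Tnf (1.34 ± 0.225 CPM in steady state and 1.19 ± 0.666 CPM at day 12), named after their values were seen, did not pass. Rising NF-kB members numbered 7, 6 and 6 without steady-state replicates 1, 2 and 3, and 6 fell without day 12 replicate 4. The list itself passed camera without steady-state replicate 2 (adjusted p = 0.0217) or 3 (0.0245), without day 12 replicate 1 (0.0238) or 3 (0.0334), and with no filter on low counts (0.00717). Immediate early and handling genes, which respond to stimulation and to tissue handling, were higher in part in the same libraries: 11 of 27 tested members rose and 3 fell (17 and 3 adjusted over the list alone) (camera adjusted p = 0.000923, and adjusted p = 0.311 with an estimated correlation). Egr1 rose from 6.56 ± 1.16 to 44.2 ± 11.5 CPM and Fosb from 0.931 ± 0.422 to 9.19 ± 1.70 CPM, while the heat shock gene Hspa1b, a near-copy of Hspa1a, fell from 201 ± 37.2 to 47.2 ± 9.94 CPM.

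Complement and coagulation genes, chemokines and adhesion genes changed in both directions. In the complement and coagulation list, 12 of 30 tested members rose and 4 fell (13 and 6 adjusted over the list alone), without passing camera (adjusted p = 0.371, median log2 fold change -0.01, mean 0.42). Fry called this list higher (fry adjusted p = 0.00564). The central complement gene C3 rose from 625 ± 61.1 to 6436 ± 1239 CPM (log2 fold change 3.36, edgeR adjusted p = 3.30e-05) and coagulation factor X (F10) from 451 ± 19.5 to 1086 ± 178 CPM. Rising members numbered 7, 5 and 7 without steady-state replicates 1, 2 and 3, and falling ones 2 without steady-state replicate 3 and 9 without day 12 replicate 4. Of the chemokines, 2 of 17 tested members rose and 3 fell (3 and 3 adjusted over the list alone) (camera adjusted p = 0.535, median -0.14, mean 0.25). Cxcl12 fell from 72.7 ± 6.70 to 7.14 ± 3.65 CPM and the platelet factor gene Pf4 from 568 ± 118 to 35.2 ± 31.1 CPM, with 80.9 CPM in day 12 replicate 2, without which the log2 fold change of Pf4 was -4.80 in place of -4.01. Ccl8 had no steady-state read and was at least 56.03-fold higher at 1.67 ± 0.457 CPM. Chemokine counts moved to 1 rising without steady-state replicate 2 or 3 or with a filter of 1 CPM, to 4 rising without day 12 replicate 1 or with DESeq2, and to 5 falling without day 12 replicate 4 or with limma-voom. Among adhesion and migration genes, 7 of 25 tested members rose and 3 fell (8 and 6 adjusted over the list alone) (camera adjusted p = 0.448, but called higher by fry with an adjusted p of 0.0307). The lymphocyte egress receptor gene S1pr1 fell from 201 ± 21.6 to 58.6 ± 12.2 CPM, whereas the tetraspanin gene Cd9 rose from 328 ± 38.1 to 569 ± 33.7 CPM. Falling adhesion genes numbered 1 without steady-state replicate 2, 5 without day 12 replicate 2 or 3 and with no filter on low counts, and 6 with DESeq2 or limma-voom.

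The lists of glycolysis and oxidative phosphorylation held many rising genes. In the glycolysis and hypoxia list, 21 of 32 tested members rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.80 (camera adjusted p = 5.08e-08, and adjusted p = 0.435 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 9.70 ± 1.82 to 48.02 ± 12.6 CPM, and the lactate exporter gene Slc16a3, which overlaps Csnk1d on the other strand and is uncertain for that reason, from 39.2 ± 4.37 to 186 ± 63.9 CPM. Of the nuclear-encoded oxidative phosphorylation genes, 18 of 38 rose and 0 fell (25 and 0 adjusted over the list alone), by small amounts such as Cox5b from 23.4 ± 0.762 to 41.4 ± 6.73 CPM and Sdhd from 62.8 ± 2.17 to 94.8 ± 4.16 CPM. This list passed camera with a median log2 fold change of 0.36 (camera adjusted p = 5.08e-08, and adjusted p = 0.311 with an estimated correlation). Its rising members numbered 8, 8 and 6 without steady-state replicates 1, 2 and 3 and 28 without day 12 replicate 4, and 1 fell without day 12 replicate 2. The share of counts from mitochondrially encoded genes moved in the same libraries, from 1.11% to 1.25% in steady state to 1.66%, 1.72% and 1.79% in day 12 replicates 1, 2 and 3, but it was 0.858% in replicate 4. None of 9 tested mitochondrially encoded genes passed edgeR's test, and 9 passed without day 12 replicate 4. Of them, 2 passed with upper-quartile factors or DESeq2, and 1 with no filter on low counts, with a filter of 1 CPM, with no robust step or without the marker genes of other cell types. The falling glycolysis member was not called with any 1 steady-state library left out or without day 12 replicate 1 or 2, and 2 fell without day 12 replicate 4.

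Stress, ribosomal and lysosomal lists held changes in both directions. Over all 15981 genes tested 20.3% passed, and the unfolded protein response and ribosomal lists held smaller shares of called members than that. In the NRF2 oxidative stress list, 3 of 23 tested members rose and 5 fell (4 and 5 adjusted over the list alone) (camera adjusted p = 0.520). Malic enzyme 1 (Me1) rose from 5.69 ± 1.81 to 31.9 ± 11.4 CPM, and the glutathione transferase gene Gstm1 fell from 41.9 ± 2.65 to 18.8 ± 1.63 CPM. Rising NRF2 members numbered 5 without day 12 replicate 4. In the unfolded protein response list, 2 of 24 tested members rose and 1 fell (2 and 1 adjusted over the list alone) (camera adjusted p = 0.116, but 0.0167 without steady-state replicate 2). Rising members of that list numbered 1 without steady-state replicate 1 or 3, without day 12 replicate 1 or with a filter of 1 CPM, and 4 without day 12 replicate 4, and with a library left out the falling member kept its call only where that library was day 12 replicate 3. Of the cytosolic ribosomal protein genes, which have many processed pseudogene copies, 1 of 51 tested members rose and 7 fell (1 and 4 adjusted over the list alone) with a median log2 fold change of -0.20 (camera adjusted p = 0.0202, and adjusted p = 0.708 with an estimated correlation). Rps14, which overlaps Ndst1 on the other strand, fell from 291 ± 13.4 to 180.1 ± 18.3 CPM. Fry did not call the ribosomal list (adjusted p = 0.127), whose mean log2 CPM in day 12 replicates 2 and 4 (6.94 and 6.95) lay above that of steady-state replicate 3 (6.91). Camera no longer called it without steady-state replicate 1 (adjusted p = 0.056), without day 12 replicate 1 (0.153) or 3 (0.0927), or with a filter of 1 CPM (0.0528). Falling ribosomal members numbered 1, 2 and 4 without steady-state replicates 1, 2 and 3, 3 without day 12 replicate 1 or 3 and 20 without day 12 replicate 4. They numbered 4 with upper-quartile factors, with library totals only, with no filter on low counts and without the marker genes of other cell types. Rising ones numbered 2 with RLE or upper-quartile factors, library totals only, a filter of 1 CPM, no robust step or DESeq2, and without day 12 replicate 1, 3 or 4. Of the lysosome and autophagy genes, 7 of 34 tested members rose and 5 fell (9 and 5 adjusted over the list alone) (camera adjusted p = 0.334). The lysosomal membrane gene Scarb2 rose from 248 ± 21.5 to 463 ± 78.9 CPM, and so did the cathepsin gene Ctsl (from 177 ± 34.05 to 438 ± 67.4 CPM). Rising lysosome members numbered 4 with any 1 steady-state library left out and 12 without day 12 replicate 4, and falling ones 2, 1 and 2 without steady-state replicates 1, 2 and 3 and 2 without day 12 replicate 1 or 2. Falling ones numbered 3 with upper-quartile factors, with no filter on low counts, with a filter of 1 CPM and without the marker genes of other cell types.

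Lipid handling, uptake and matrix genes changed in both directions. The cholesterol synthesis list held a smaller share of called members than the 20.3% of all genes tested. In the lipid-associated macrophage list, 5 of 26 tested members rose and 10 fell (5 and 10 adjusted over the list alone) (camera adjusted p = 0.354). Cd63 fell from 44.3 ± 11.7 to 6.06 ± 2.52 CPM and the protease gene Lgmn from 649 ± 92.1 to 343 ± 26.8 CPM, while Spp1, which encodes osteopontin, rose from 0.979 ± 0.501 to 125 ± 51.1 CPM (log2 fold change 6.99, edgeR adjusted p = 0.000142). The rising members of that list numbered 3 with a filter of 1 CPM. Among cholesterol efflux and LXR or PPAR targets, 3 of 21 tested members rose and 5 fell (4 and 9 adjusted over the list alone) (camera adjusted p = 0.357, but called lower by fry with an adjusted p of 0.0461). The fatty acid carrier gene Fabp4 fell from 234 ± 26.9 to 69.8 ± 24.6 CPM and Acaca, the first enzyme of fatty acid synthesis, from 349 ± 24.7 to 191 ± 16.99 CPM. The falling members of that list numbered 3 with any 1 steady-state library left out and with no filter on low counts. Of the cholesterol synthesis genes, 3 of 24 tested members rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.776), with Mvd at 9.75 ± 0.301 CPM in steady state and 28.3 ± 7.20 CPM at day 12. The rising cholesterol synthesis members numbered 1 without steady-state replicate 3. The falling ones numbered 0 without steady-state replicate 1 or 2 or day 12 replicate 1, and 2 without day 12 replicate 2 or 4, with no filter on low counts, with DESeq2 and with limma-voom. Among efferocytosis and phagocytic receptors, 7 of 27 tested members rose and 11 fell (7 and 13 adjusted over the list alone) (camera adjusted p = 0.162). The integrin gene Itgb3 fell from 66.4 ± 9.39 to 8.04 ± 2.68 CPM and the scavenger receptor genes Colec12 and Stab1 (the latter named after its values were seen) fell from 131 ± 14.2 to 21.9 ± 7.97 CPM and from 406 ± 132 to 55.2 ± 20.7 CPM, whereas the oxidised lipid receptor gene Olr1 rose from 5.57 ± 2.00 to 25.8 ± 4.16 CPM. The rising members of this list numbered 4 without steady-state replicate 3. In the tumour-associated macrophage and matrix list, 9 of 28 tested members rose and 6 fell (10 and 8 adjusted over the list alone) (camera adjusted p = 0.794, median log2 fold change -0.18, mean 0.17). The matrix protein gene Tgfbi fell from 1028 ± 51.5 to 57.04 ± 35.8 CPM, and the membrane-bound protease gene Mmp14 rose from 0.966 ± 0.205 to 4.75 ± 1.37 CPM.

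Cell cycle genes varied widely between libraries, with few single calls. Of 54 members tested, 0 rose and 2 fell (0 and 1 adjusted over the list alone), and the list's median log2 fold change was -1.31 (camera adjusted p = 1.00e-05, and adjusted p = 0.708 with an estimated correlation). Fry did not call a change in a common direction (adjusted p = 0.218). The list's mean log2 CPM was 4.36, 3.60 and 2.84 in steady-state replicates 1, 2 and 3 and 0.878, 3.31, 0.948 and 3.12 in day 12 replicates 1, 2, 3 and 4, so the groups overlapped and only day 12 replicates 1 and 3 lay below all of steady state. Racgap1, needed for cytokinesis, fell from 57.3 ± 11.99 to 23.6 ± 5.45 CPM (edgeR adjusted p = 0.00248). Ect2, its partner, fell from 10.1 ± 5.55 to 2.97 ± 1.81 CPM (adjusted p = 0.0420), a call lost without steady-state replicate 1 (0.164) or 2 (0.089) and without day 12 replicate 1 (0.0865), 3 (0.0712) or 4 (0.0958). It was also lost with library totals only (0.0515) and with no filter on low counts (0.141). Top2a, named after its values were seen, was at 77.1 ± 50.4 CPM in steady state and 27.9 ± 21.5 CPM at day 12 and did not pass. Mki67 was at 177, 88.7 and 53.3 CPM in steady-state replicates 1, 2 and 3 and at 13.4, 72.7, 15.2 and 49.8 CPM in day 12 replicates 1, 2, 3 and 4.

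**Figure D3:**
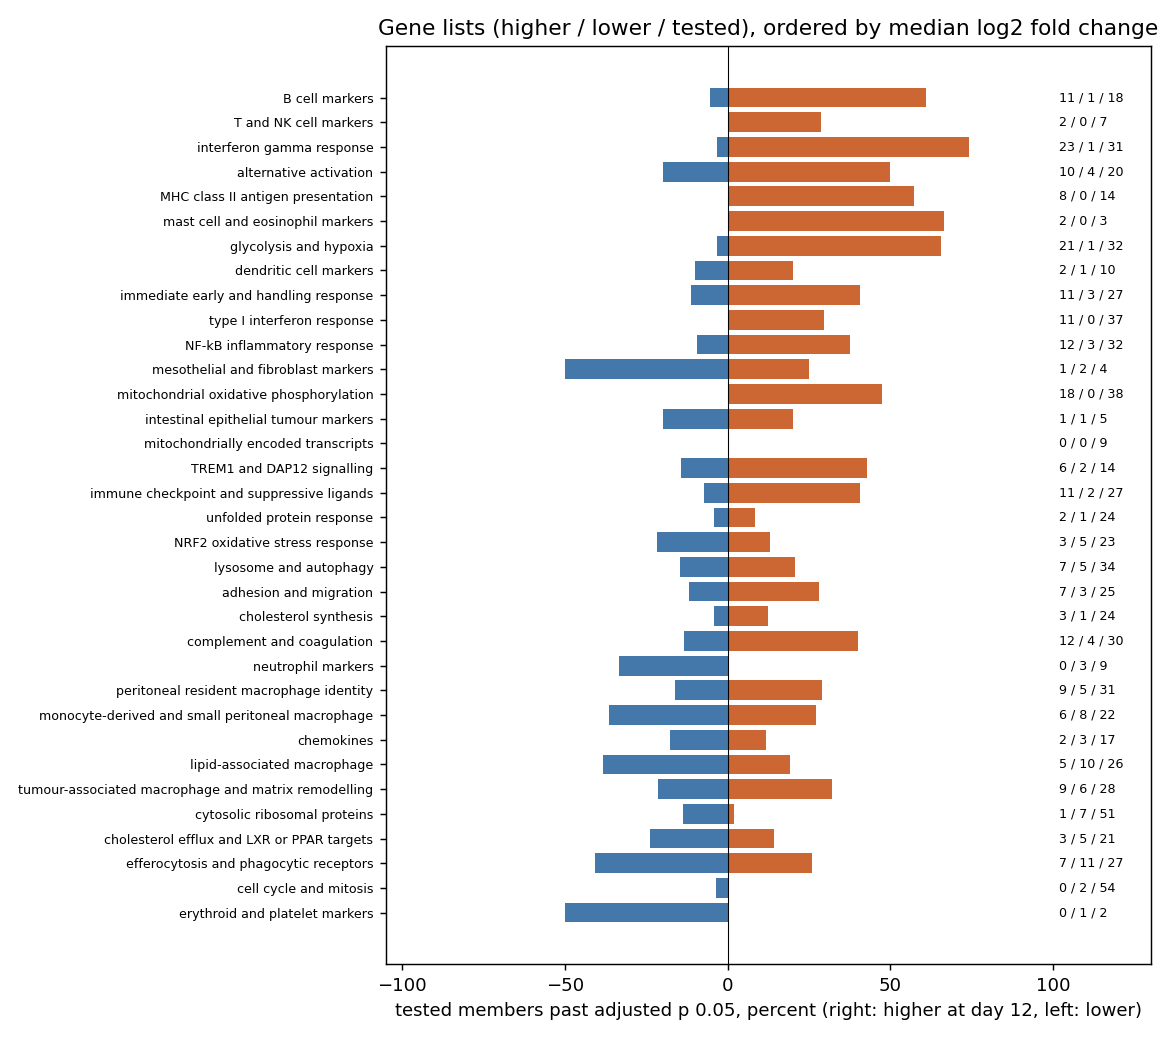
Bars give the percentage of tested members of each of the 34 lists that passed an adjusted p of 0.05, to the right (orange) higher at day 12 and to the left (blue) lower, with the numbers higher, lower and tested at the right edge. Lists are ordered by median log2 fold change, with B cell markers at the top and erythroid and platelet markers, of which 2 were tested, at the bottom.

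Over all 34 lists, 12 passed camera at an adjusted p of 0.05 with a preset correlation of 0.01 between genes. With an estimated correlation 0 passed, while limma's fry called 17 for a change in a common direction and 30 for change in either direction. Fry compares a list with no change, not with other genes.

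Markers of other cell types were summed per library and compared by an exact two-sided permutation test over the 35 splits of the 7 libraries, whose smallest possible p is 0.0286. Platelet and erythroid markers were 569 ± 118 CPM in steady state and 36.3 ± 30.7 CPM at day 12 (exact p = 0.0286), and nearly all of that was Pf4, which macrophages also express. Mast cell and eosinophil markers were 78.8 ± 11.6 and 161 ± 29.5 CPM (exact p = 0.0286, and 0.0571 with library totals only), mostly the histidine decarboxylase gene Hdc (from 77.00 ± 11.6 to 159 ± 29.4 CPM). The sums of B cell markers (524 and 449 CPM, exact p = 0.0571) were dominated by Cd37 and Bank1, while Cd79a (chosen, like Cd37, after its values were seen) was at 1.21 ± 0.291 CPM in steady state and 2.37 ± 1.09 CPM at day 12. By camera the B cell list passed with a median log2 fold change of 2.04 (camera adjusted p = 1.27e-05, and adjusted p = 0.671 with an estimated correlation), with 15 members higher and 1 lower adjusted over the list alone. T and NK cell markers were at 3.35 and 6.69 CPM (exact p = 0.143). That list passed camera (camera adjusted p = 0.0398, and adjusted p = 0.671 with an estimated correlation), but not without day 12 replicate 2 (0.898), 3 (0.418) or 4 (0.678) or steady-state replicate 2 (0.0785) or 3 (0.0542), nor with library totals only (0.0524), upper-quartile factors (0.0609) or a filter of 1 CPM (0.676). Of its 7 tested members 2 rose and 0 fell (4 and 0 adjusted over the list alone). The rising ones numbered 0 without day 12 replicate 2, 3 or 4 or with a filter of 1 CPM, 1 without steady-state replicate 2, and 4 without day 12 replicate 1, with no filter on low counts or with DESeq2. The exact p-values were 0.2 for neutrophil markers (2158 and 1845 CPM), 0.457 for dendritic cell markers (387 and 481 CPM) and 0.0571 for mesothelial and fibroblast markers (12.1 and 8.57 CPM). They were 0.743 for intestinal epithelial tumour markers (8.28 and 8.93 CPM) and 0.429 for monocyte-derived macrophage genes (46015 and 36465 CPM). The last sum was mostly Lyz2 in steady state and Chil3 at day 12, which changed in opposite directions, and the dendritic cell sum likewise joined the fall of Fscn1 with the rise of Naaa. Cd209a, a member of both lists named after its values were seen, stood at 37.1 CPM in steady state and 172 CPM at day 12. It did not pass (edgeR adjusted p = 0.0612). Padi4, named after its values were seen, made up most of the neutrophil sum and Krt7 most of the mesothelial sum. Adjusted over the 9 lists, the lowest p was 0.129.

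By single genes, 0 of 9 neutrophil markers rose and 3 fell (2 and 3 adjusted over the list alone), with Csf3r from 440.2 ± 8.41 to 159.6 ± 39.9 CPM and Mmp9 from 22.8 ± 4.14 to 0.899 ± 0.720 CPM. Of the dendritic cell markers, 2 of 10 tested members rose and 1 fell (4 and 1 adjusted over the list alone): Naaa rose from 64.7 ± 3.82 to 209 ± 52.4 CPM and Fscn1 was the fall. Of the mast cell and eosinophil markers, 2 of 3 tested members rose and 0 fell (2 and 1 adjusted over the list alone), of the mesothelial and fibroblast markers, 1 of 4 tested members rose and 2 fell (2 and 2 adjusted over the list alone), and of the erythroid and platelet markers, 0 of 2 tested members rose and 1 fell (0 and 1 adjusted over the list alone). Of the intestinal epithelial markers, 1 of 5 tested members rose and 1 fell (2 and 1 adjusted over the list alone): the cadherin gene Cdh1 rose from 0.129 ± 0.0182 to 2.00 ± 0.658 CPM and the Wnt target Axin2 fell from 3.81 ± 0.173 to 1.26 ± 0.219 CPM. The other members of these lists had too few reads to be tested. Rising mesothelial members numbered 2 with any 1 steady-state library left out, 3 with no filter on low counts, 4 with DESeq2, and 0 without day 12 replicate 1, 3 or 4 or with a filter of 1 CPM. Falling ones numbered 0 without steady-state replicate 1 or with a filter of 1 CPM, and 1 without steady-state replicate 2 or 3 or day 12 replicate 1, 2 or 4, with RLE or upper-quartile factors, or with no robust step. Rising neutrophil markers numbered 1 without day 12 replicate 2 or 4, with no filter on low counts, with a filter of 1 CPM or with no robust step, and 2 with DESeq2. Rising dendritic cell markers numbered 1 without steady-state replicate 1 and 5 with DESeq2. Rising mast cell markers numbered 1 without steady-state replicate 1 or 2 or day 12 replicate 2, and 1 mast cell marker fell with DESeq2. Rising epithelial markers numbered 2 without steady-state replicate 1 or day 12 replicate 4, with no filter on low counts or with limma-voom, and 3 with DESeq2. Camera called none of these 6 lists (adjusted p = 0.405 for neutrophil, 0.357 for dendritic cell, 0.348 for mast cell, 0.761 for mesothelial (0.0278 with no filter on low counts), 0.256 for erythroid and 0.425 for epithelial markers), nor the mitochondrially encoded genes (0.162, but 3.27e-05 without day 12 replicate 4). Fry, which compares a list with no change, called the mast cell (fry adjusted p = 0.00564), mesothelial (0.0107) and epithelial (0.0461) lists higher. It called the erythroid list lower (0.00379), and the neutrophil (0.0602) and dendritic cell (0.783) lists did not pass it.

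**Figure D4:**
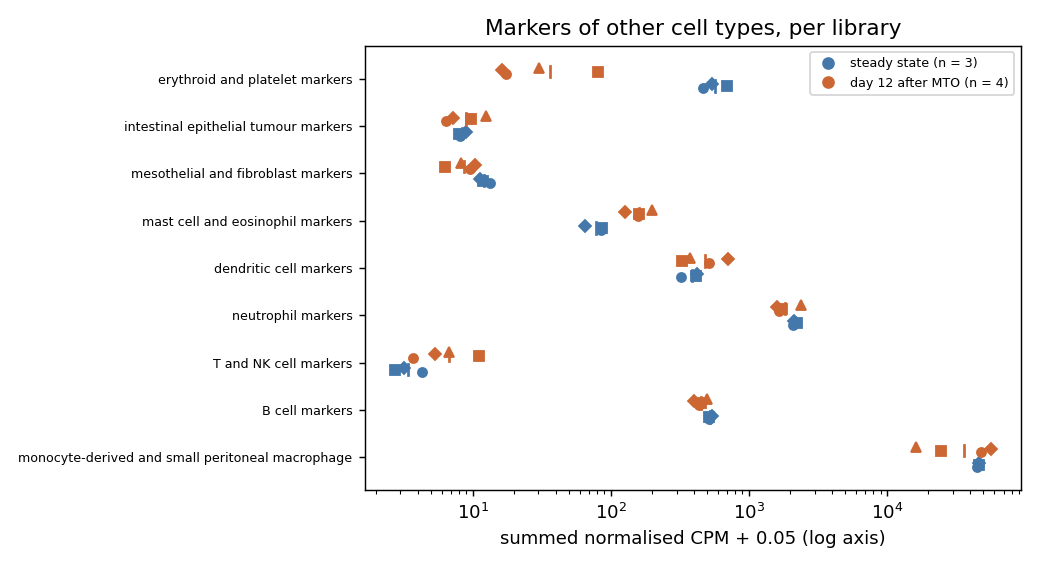
Summed normalised CPM (plus 0.05, log axis) of the markers of 9 other cell types in each library, blue for steady state (n = 3) and orange for day 12 (n = 4), with bars at group means and marker shapes for the replicate number. The erythroid and platelet sums and the mast cell and eosinophil sums reached the smallest exact p, 0.0286.

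The steady-state libraries lay close together and the day 12 libraries did not. Pearson correlations of log2 CPM were 0.988 to 0.990 among steady-state libraries, 0.968 to 0.985 among day 12 libraries and 0.931 to 0.960 between groups, computed across genes, which are not independent replicates. The first principal component held 64.3% of the variance and placed the steady-state libraries at -65.3, -65.5 and -63.3 and the day 12 libraries at 60.5, 25.1, 61.5 and 47.0. Day 12 replicate 2 thus lay nearest to steady state, and Apoe, Lyz2 and Tgfbi were highest in that library among the day 12 libraries. Replicate 4 stood apart on the next component (15.05% of the variance, at 53.7). Without day 12 replicate 2 the count of changed genes was 3136, and without replicate 4 it was 4599. No pair of libraries agreed within sampling noise, as copies of a single library would.

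**Figure D5:**
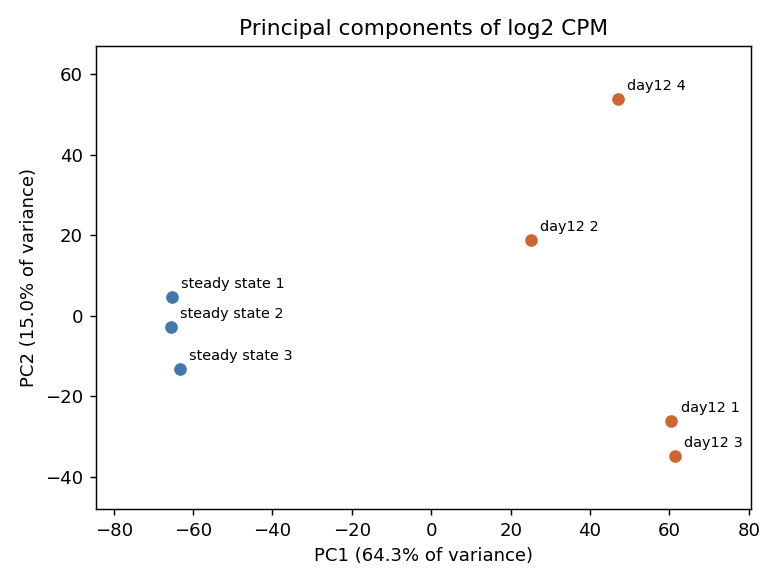
Libraries on the first and next principal components of log2 CPM, which hold 64.3% and 15.05% of the variance, blue for steady state and orange for day 12. The 3 steady-state libraries lie between -65.5 and -63.3 on the first component and the 4 day 12 libraries between 25.1 and 61.5.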

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

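Of the tests in this part, the comparison of day 12 replicate 2 in rising genes was chosen after the result was seen, while the split count and the comparison in falling genes were written before.

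Of the 35 splits of the 7 libraries into 3 and 4, 1 gave as many changed genes as the real grouping, namely the real grouping itself with 3242, and the highest of the others gave 12. The smallest p that an exact count over 35 splits can give is 0.0286, so chance in the grouping of libraries is unlikely for that count but not excluded. A day of sorting or library preparation shared within a group would give the same result.

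Day 12 replicate 2 lay nearer to steady state than the other day 12 libraries. If steady-state cells had been mixed into that library, falling and rising genes would both be shifted by the same share of such cells. Among 39 genes that fell over 8-fold in the other day 12 libraries, the median implied share was 0.0858 (quartiles 0.0571 and 0.166). Of them, 7.69% (3 genes) lay below 0.5 of the level that share would bring, so the falling genes do not contradict a small admixture. The 62 genes that rose over 8-fold implied a median share of 0.467 (quartiles 0.342 and 0.602), far above that of the falling genes, where an admixture alone would give like shares. Both sets were picked by their fold in a fit without replicate 2, which by itself tends to place the library left out nearer to steady state. No other day 12 library was left out in the same way for comparison, so these shares do not decide on an admixture. A weaker response to the injection in that library's cells remains open and was not tested.

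The remaining values came from Dixon's test, in which the gap between the lowest or highest day 12 library and its nearest neighbour, divided by the range of the 4, exceeded its 95% critical value. The ratios of genes and lists were computed on log2 CPM with a prior count of 2, while gene levels below are plain CPM. It marked 16 of 235 values (6.81%), where chance marks about 1 in 20, and the library apart was day 12 replicate 1, 2, 3 or 4 in 2, 5, 1 and 8 of them. In replicate 4, Il6 was low at 13.1 CPM against 21.7 to 22.7 CPM (ratio 0.922). Mmp8 was low there too, at 0.0290 against 0.0503 to 0.0530 CPM (0.898), but with 7 reads in all 4 libraries together it lay under the floor of detection, and that mark carries no weight. Me1 was high in replicate 4 at 48.9 against 24.96 to 27.5 CPM (0.857). Wfdc21 stood at 17.1 CPM there against 1.26 to 1.97 (0.830), and Alox15 at 10846 against 9398 to 9466 CPM (0.950). The mitochondrial gene mt-Nd4l was low in replicate 4 at 169.8 against 278 to 298 CPM (0.881). The mean log2 CPM of mitochondrially encoded transcripts was 8.95 in replicate 4 and 9.94 to 9.97 in the others (0.966), and that of the TREM1 and DAP12 list was 5.49 against 4.73 to 4.81 (0.897). In replicate 2, Pglyrp1 was low at 59.8 against 124 to 139 CPM (0.864). C4b, which like Lpl and Alox15 was chosen after its values were seen, was low there at 17155 against 23323 to 23997 CPM (0.915), and Itga2b at 0.276 against 0.662 to 0.784 CPM (0.832). Lpl was high in replicate 2 at 91.1 against 4.67 to 6.41 CPM (0.894), and the mean log2 CPM of B cell markers was 2.03 against 0.86 to 1.06 (0.830). In replicate 1, Apbb1 was low at 0.0265 against 0.605 to 0.779 CPM (0.899), and Oas2 high at 411 against 316 to 328 CPM (0.853). In replicate 3, Gbp7 was low at 135 against 186 to 198 CPM (0.830).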

How the results depend on the processing

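The removal of length and GC trends was chosen after the data were seen, and the other tests of this part were planned before. No gene called both in the main test and under an alternative changed sign, and the count of 3242 changed genes lay between 2964 and 3981 under other scalings, filters and tools. With 1 library left out, changed genes numbered 1761 to 4599, rising ones 857 to 2188, falling ones 904 to 2411 and those passing the 1.5-fold test 676 to 1188. The low ends came with a steady-state library removed, leaving 2 against 4 libraries, and the high end of 4599 came without day 12 replicate 4; the cause was not tested. Of 191 genes considered, 158 passed in the main test, 132 of these passed with any 1 library left out and 125 under all alternatives that tested them, while 14 of the 33 others passed under some alternative. The 12 lists past camera became 0 with an estimated correlation, and 11 to 13 when a library was left out. Of 635 list results under alternatives, 583 kept their side of the threshold, 32 lost it and 20 gained it, and 236 of 1224 counts of rising or falling list members moved by over 1.5 times. With length and GC trends removed, the T and NK list no longer passed camera (adjusted p = 0.0612), while the NF-kB (0.0387) and mitochondrially encoded (0.0123) lists did. The median log2 difference of the T and NK list did not shrink, at 1.434 before that removal and 1.585 after it. Spearman correlations of log2 fold change, across genes, were -0.15 with length and 0.10 with GC content before that step. The replicate number as a block gave 4278 changed genes (1989 higher, 2289 lower), 955 by the 1.5-fold test, and 4315 with upper-quartile factors as well. Day 12 replicate 4 has no partner, so this fit rests on 3 libraries of each group. Deviations from the group mean of same-numbered libraries correlated at -0.14, 0.01 and 0.20, and only steady-state replicate 3 correlated best with its own number, while replicate 1 correlated best with day 12 replicate 2 (0.19) and replicate 2 with day 12 replicate 4 (0.03), so the numbers were not taken as pairs. For sums of other cell types, leaving out a library leaves too few splits for an exact p under 0.05, so those tests say nothing about stability. In simulation with 3 and 4 libraries at this depth, with the same dispersion of each gene in both groups, 16.7% of genes changed 1.5-fold were recovered. Of the 111 simulated calls, 10 (9.01%) were false, at an adjusted p threshold of 0.05. The day 12 libraries spread more widely than those of steady state, and recovery and false calls under such unequal spread were not tested.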

Other observations

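All tests of explanations in this part were chosen after the results were seen, while the calls of single genes came from the planned edgeR test.

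A set of 96 genes rose at day 12 from at most 30 reads summed over the 3 steady-state libraries, to at least 1 CPM on average. Their median at day 12 was 1.68 CPM, and 3 of them (Chil4, Mall and Trim43a) exceeded 50 CPM. Besides genes already named, the set held the angiopoietin-like gene Angptl2 (24.3 ± 11.8 CPM at day 12, 27 reads in steady state), the mucin gene Muc20 (9.36 ± 5.06 CPM), the leptin receptor gene Lepr (8.27 ± 4.90 CPM) and the protease inhibitor gene Cst7 (7.42 ± 1.90 CPM). Timd2, a relative of Timd4, had no steady-state read, reached 4.49 ± 2.47 CPM and was at least 151-fold higher (edgeR adjusted p = 0.00101). Trim43c, of the same family as Trim43a, had none either and reached 3.05 ± 2.31 CPM. The lectin genes Cd209e (3.40 ± 2.65 CPM) and Cd209c (2.50 ± 1.34 CPM) and the metalloprotease inhibitor gene Timp1 (2.68 ± 1.04 CPM) belonged to it too. These genes were chosen after their values were seen.

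RNA from tumour epithelium carried along in the sort could bring genes that resident macrophages lack in steady state, although the gates on CD11b and Tim4 should remove such cells. Cdh1, of the epithelial list, was itself in the set at 2.00 CPM, but the median of 10 abundant epithelial transcripts that include it was 0.0339 of the median of the 96 genes. The set was limited to genes of at least 1 CPM at day 12, while these transcripts were taken without a limit, which by itself lowers that ratio. Krt18 came next at 0.315 CPM and Epcam, named after its values were seen, was at 0.0670 CPM, which argues against that source for the set as a whole. For Chil4, reads shared with the far more abundant Chil3 are a candidate explanation, since the ratio of Chil3 to Chil4 was 39.7 to 44.7 in the 4 day 12 libraries (coefficient of variation 5.39%) while Chil3 itself varied 5.48-fold, as sharing would give, although joint regulation of the neighbouring genes would give the same. A response of the macrophages to the injection, the difference the design names, stays open and was not tested.

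The rise of MHC class II transcripts might come from other class II positive cells in the sort, although its gates on CD11b and Tim4 should remove most of them. The sort also used an antibody to MHC class II, but the gate drawn with it is not given in the sources used here. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (the last 2 chosen after their values were seen) were together 3106 CPM higher at day 12, while the 11 B cell markers that rose were together 24.1 CPM higher, a ratio of 0.00775, which argues against B cells as the main source. Called members of the lists of dendritic cells and of monocyte-derived macrophages went both ways, with ratios of rising to falling members of 2 (over 3 called members) and 0.75. Resident macrophages also express many of these genes, so dendritic cells, monocyte-derived macrophages and a change within resident cells cannot be told apart.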
